A study of Homo sapiens with 6 samples.

How the data were processed

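RNA of 3 libraries of parental HCC827 and 3 of HCC827OR was sequenced, per the labels, from libraries made with a TruSeq kit. Groups and replicate numbers came from the sample titles. The deposited table gives, for each human Ensembl gene, a normalized expression signal for each library, a mean per line, a ratio (fold change), a log2 fold change, a p-value and an adjusted p-value from the authors. The authors' fold change, log2 fold change and p-values carry no named test in the file headers. The name of the expression signal's unit, the normalization, the gene annotation and the aligner are not given in the file headers, and the deposited signal values have 2 decimals, so reads could not be recovered and depth is unknown. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse build mm8 were used, which conflicts with the human gene IDs, and the extraction protocol in the labels speaks of retinas. These notes therefore leave the origin of the values open, and no step is taken from them here. All genes met an adjusted p below 0.05 and an absolute log2 fold change of at least 1, so genes that did not differ are not analysed here.

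Symbols were taken by gene ID from a symbol table, which matched 4414 IDs and left 25 unmatched. This restored 7 gene names that had been turned into dates. Positions are those of GENCODE release 29 on GRCh38, found by gene ID for 4422 genes, and 3488 genes were protein-coding. The only build named is the mouse build of the submitters' processing notes, and a human build behind the authors' values is not given in the sources used here. Use of strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty.

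Values were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend, for genes with a value of at least 1 in at least 3 of the 6 libraries. This kept 3332 genes and left 1107 untested. Benjamini-Hochberg adjusted p below 0.05 was the threshold, and fold changes on this scale understate the change of low genes. Linear folds are ratios of group means, and none is given against a line listed at 0. Before the data were examined 31 gene lists were fixed, and the 21 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over those lists. The same fixed design named EGFR, MET and AXL, the 8 largest rises and 8 largest falls, up to 4 members of each list with the smallest adjusted p and all members of the 2 receptor lists. It also named any member needed to show which way a list went. Some genes that the rule names are not reported here. The 8 largest were taken among called genes whose 3 libraries of one line all lay above those of the other and whose higher mean was at least 2, a minimum written for FPKM-like units and used here on an unnamed one.

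Tests were checked on simulated data with the real genes' means and spreads. Of 100 genes changed 2-fold 70% were called, of 100 changed 4-fold 91%, and of 3132 unchanged genes 8 were called. The simulation changed 200 genes and drew each gene independently, whereas the real genes had all been picked for differing. These rates therefore show that the test runs as intended and are not those of the real data. Alternatives covered scaling, filter, pseudocount, trend, replicate block, threshold, the list test and leaving out each library. A test of the direction of the authors' calls per list was added after the data were seen. Count-based tests were not run because the table holds no counts. Regions were scanned with Python 3.11.15 and pandas 2.3.3 over windows of 20 consecutive protein-coding genes, against 1000 shuffles of 2 kinds. One placed the table's genes at random among 19864 protein-coding genes, and the other shuffled the directions over the table's own genes.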

Results

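Expression of mRNA was measured by RNA sequencing in 6 libraries of the human lung adenocarcinoma line HCC827, which carries an activating mutation of the receptor tyrosine kinase EGFR. There were 3 libraries of the parental line and 3 of HCC827OR, a derivative selected with osimertinib, an inhibitor of mutant EGFR. Selection used steps of 10, 50, 100 and 500 nM and then 1 and 5 µM, each held for 1 month. The deposited table held 4439 genes, and every one of them had been called different by the authors, 2392 higher and 2047 lower in the resistant line. Whether osimertinib was present at harvest is not stated. Library depth is unknown, since the table gives normalized expression values without counts. Over the table's genes the values summed to 120825, 115790 and 145175 in parental libraries 1 to 3 and to 151604, 149956 and 152065 in resistant libraries 1 to 3. Normalized expression values are given as mean ± SD of n = 3 libraries per line.

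The comparison of the resistant with the parental line asked which transcripts differed after selection. In the resistant line EGFR fell 22.8-fold, from 558 ± 80.3 to 24.5 ± 0.706, and the receptor MET fell 2.89-fold, from 279 ± 39.8 to 96.5 ± 1.24, while the receptor AXL rose 21.4-fold, from 2.56 ± 0.401 to 54.9 ± 2.35. By limma, 33 of 33 epithelial genes tested fell and 19 of 19 mesenchymal genes tested rose. Of single genes tested by limma, 21 of 21 of cholesterol synthesis and 19 of 22 interferon-stimulated ones fell, and 17 of 19 inflammatory ones rose. Of 3332 genes with a value of at least 1 in at least 3 libraries, 1749 were higher and 1500 lower by limma at an adjusted p below 0.05, and 83 were not called. At a change of at least 2-fold the counts were 1434 higher and 1110 lower. Because the authors had already picked these genes for differing between the same libraries, these counts are not independent evidence of a difference. The list tests rest on the same genes. Camera compared each list only with other genes picked for differing, so its p-values do not measure enrichment among all expressed genes. Nothing in the labels says that the libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

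The epidermal growth factor receptor gene EGFR (ENSG00000146648; chromosome 7, 55019021 to 55211628 in GRCh38) had values of 630.91, 570.74 and 471.79 in the parental libraries and 24.35, 23.81 and 25.21 in the resistant libraries. Its log2 fold change was -4.45 (SE 0.135, limma adjusted p = 7.40e-07). MET, the hepatocyte growth factor receptor (ENSG00000105976; chromosome 7, 116672390 to 116798386), had values of 259.44, 252.18 and 324.41 against 95.13, 97.54 and 96.87, a log2 fold change of -1.51 (SE 0.131, limma adjusted p = 3.55e-05). AXL, a receptor of the ligand GAS6 (ENSG00000167601; chromosome 19, 41219203 to 41261766), had values of 2.6, 2.94 and 2.14 against 57.51, 52.95 and 54.23, a log2 fold change of 3.98 (SE 0.132, limma adjusted p = 9.24e-07).

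Of 7 tested EGFR family members and ligands, 5 fell and 2 rose. The receptor ERBB3 fell 6.82-fold, from 59.6 ± 13.5 to 8.75 ± 0.576, and the ligand AREG fell 8.41-fold, from 142 ± 15.4 to 16.9 ± 1.55. The ligands BTC and TGFA also fell, BTC from 8.2 ± 1.96 to 3.08 ± 0.205 and TGFA from 23 ± 18 to 4.66 ± 0.358. Parental library 3 held 43.7 for TGFA against 14 and 11.22 in the other parental libraries, and without it the fold was 2.71 in place of 4.93. The ligands HBEGF and NRG1 rose, from 3.36 ± 0.144 to 7.85 ± 0.743 and from 6.31 ± 1.93 to 17.4 ± 2.8. As a list the family did not pass camera (adjusted p = 0.163).

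Among 14 tested members of the list of other receptor tyrosine kinases and ligands, 7 rose, 6 fell and 1 was not called. The fibroblast growth factor receptor FGFR1 rose 9.47-fold, from 8.51 ± 3.16 to 80.6 ± 6.34, and PTK7, EPHA4, ROS1 and GAS6 also rose, GAS6 from 11 ± 3.26 to 25.5 ± 2.96. The growth factor gene IGF2, whose reads overlap the INS-IGF2 locus and are therefore uncertain, was 0.123 ± 0.125 and 24.6 ± 0.332, a log2 fold change of 4.52, and its parental mean was 0.06 without parental library 3. MST1R fell 6.09-fold, from 26.4 ± 1.5 to 4.33 ± 0.538, and DDR1, EPHA2, KITLG and MERTK also fell, MERTK from 11.9 ± 3.8 to 1.45 ± 0.621. FGFR3 had values of 5.59, 4.66 and 20.09 against 3.85, 3.48 and 3.65 and was not called (limma adjusted p = 0.0763). Without parental library 3 its log2 fold change was -0.39 in place of -0.99, with a limma adjusted p of 0.0198 (range over the alternatives 0.0198 to 0.151). The list's median log2 fold change was 0.10 and its mean 0.43, while camera ranked it lower than the other genes without passing (adjusted p = 0.979).

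Transcripts that report output of the MAPK cascade fell in 8 of 9 tested (9 of 20 members in the table, camera adjusted p = 0.0129, and adjusted p = 0.538 with an estimated correlation). The ERK phosphatase DUSP6 fell 20.6-fold, from 44.2 ± 8.64 to 2.15 ± 0.347. DUSP5 fell 5.91-fold, from 33 ± 5.77 to 5.58 ± 0.363, and the cyclin gene CCND1 fell 3.19-fold, from 104 ± 6.5 to 32.5 ± 1.3. The feedback inhibitor SPRY4 fell from 4.77 ± 1.19 to 0.4 ± 0.0964. The exception was IER3, an early response gene also induced by NF-kB, which rose from 95.8 ± 36.9 to 234 ± 8.83. Parental library 3 had a median log2 value 0.45 above the mean of the other parental libraries in this list, against 0.13 over all tested genes. With genes filtered at a value of at least 5 the camera adjusted p was 0.055 (range over the alternatives 0.00757 to 0.055).

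**Figure D1:**
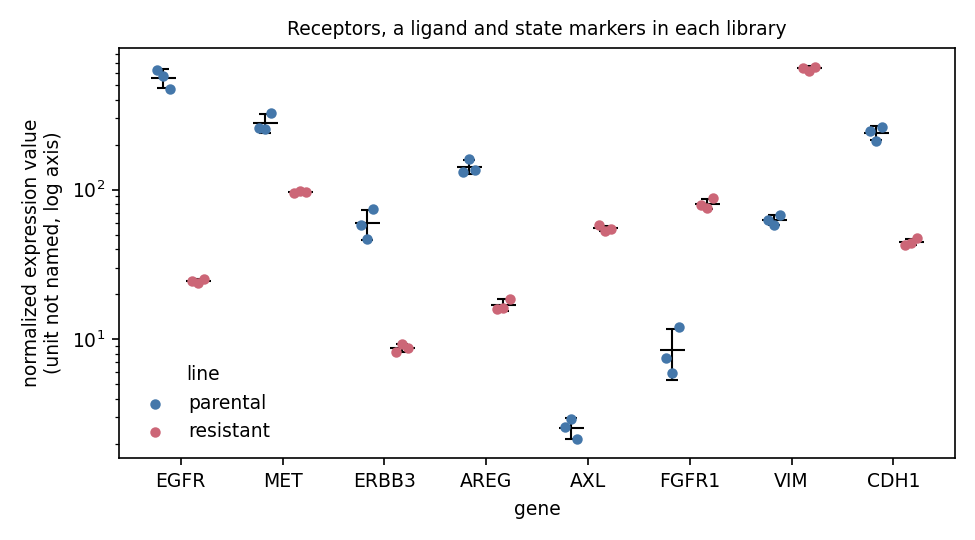
Normalized expression values (unit not named, log axis) of 8 genes, with points for the 3 parental and 3 resistant libraries, horizontal marks for means and bars for SD. EGFR, MET, ERBB3, AREG and CDH1 lay lower in all 3 resistant libraries, and AXL, FGFR1 and VIM higher.

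Large rises, taken by the rule for named genes, included genes listed at 0 in the parental line. The natriuretic peptide gene NPPB (chromosome 1, 11857464 to 11858931), the smooth muscle calponin gene CNN1 (chromosome 19, 11538717 to 11550323) and the protease inhibitor gene SERPINB2 (chromosome 18, 63871692 to 63903890) were listed at 0 in all 3 parental libraries. Their values in the resistant libraries were 259 ± 11.3, 73.1 ± 1.4 and 54.3 ± 1.32. The chemokine CXCL6 (chromosome 4, 73836497 to 73849064) had 0.24, 0.04 and 1.76 in parental and 366.4, 391.03 and 373.82 in resistant libraries. IGFN1 (chromosome 1, 201190825 to 201228952) was 0.427 ± 0.263 and 130.0 ± 8.38, PLAC8 (chromosome 4, 83090048 to 83137075) 0.373 ± 0.32 and 97.7 ± 6.98, and the matrix gene FBLN1 (chromosome 22, 45502238 to 45601135) 0.27 ± 0.0755 and 67 ± 1.76. The log2 fold changes of these 7 genes ran from 5.74 to 8.02, and that of NPPB had an SE of 0.109 (limma adjusted p = 4.27e-08). Without parental library 3 the parental means of CXCL6 and IGFN1 were 0.14 and 0.275 in place of 0.68 and 0.427, and without parental library 1 that of PLAC8 was 0.21.

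The 8 largest falls included AGR2, MUC5B and S100A14. AGR2, a disulfide isomerase of mucus-producing cells (chromosome 7, 16791811 to 16833433), fell from 147 ± 7.11 to 0.12 ± 0.208, a log2 fold change of -7.06 (SE 0.159, limma adjusted p = 4.14e-07). Its resistant mean rested on resistant library 1, with 0.36, and AGR2 was listed at 0 in the other resistant libraries. S100A14 (chromosome 1, 153614255 to 153616986) fell from 136 ± 22.3 to 0.237 ± 0.0757 and the surfactant-associated gene SFTA2 (chromosome 6, 30931353 to 30955636) fell from 197 ± 3.64 to 1.19 ± 0.922. KRT16P1, a keratin pseudogene that shares sequence with KRT16 and is therefore uncertain (chromosome 17, 18432051 to 18442895), fell from 123 ± 19 to 0.103 ± 0.0751. The resistant mean of SFTA2 was 0.655 without resistant library 3, and that of KRT16P1 0.065 without resistant library 2. In the remaining 4 genes parental library 3 lay far above the other parental libraries. The mucin MUC5B (chromosome 11, 1223066 to 1262172) had 116.2, 86.14 and 440.77 in parental libraries against 0.28 ± 0.195 in resistant ones, and its parental mean without library 3 was 101 in place of 214. Its log2 fold change was -6.31 without that library in place of -7.02. On this scale of log2(value + 1) that was a smaller fall than those of AGR2, S100A14, KRT16P1 and SFTA2. By ratio of means without parental library 3 the order differed for SFTA2, MUC5B falling 361-fold and SFTA2 165-fold. The resistant mean of MUC5B was 0.17 without resistant library 3, and that of LY6D 1.08 without resistant library 2. The defensin DEFB4A (chromosome 8, 7894629 to 7896711), which has near-identical copies and is uncertain, had 116.69, 113.02 and 674.4 against 1.62 ± 1.03, OLFM4 (chromosome 13, 53028759 to 53052057) 59.01, 55.71 and 335.84 against 0.38 ± 0.171, and LY6D (chromosome 8, 142784880 to 142786592) 104.44, 100.27 and 410.12 against 1.68 ± 1.24. Without parental library 3 the parental means of these 3 genes were 115, 57.4 and 102, and LY6D lies on chromosome 8 beyond 50 Mb, where most genes of the table fell. Their log2 fold changes without that library were -5.56, -5.41 and -5.39 in place of -6.40, -6.25 and -6.05.

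Epithelial genes fell as a group, 33 of the list's 36 members being in the table and all 33 lower (camera adjusted p = 1.08e-10, and adjusted p = 0.148 with an estimated correlation). The adhesion genes EPCAM and CDH1 (E-cadherin) fell 29.1-fold and 5.38-fold, from 360.0 ± 38.6 to 12.4 ± 0.749 and from 240.1 ± 25.3 to 44.6 ± 2.19. The trafficking genes RAB25 and MAL2 fell from 68.7 ± 5.74 to 0.137 ± 0.118 and from 175 ± 20.4 to 3.55 ± 0.529, MAL2 lying on chromosome 8 beyond 50 Mb, where 113 of the table's genes fell and 19 rose. The keratin KRT18 fell 2.22-fold and was 999 ± 7.08 in the resistant line. CDH1 and KRT18 were chosen after their values were seen. Of the 40 mesenchymal genes 23 were in the table, and 19 of 19 tested were higher (camera adjusted p = 1.02e-05, and adjusted p = 0.148 with an estimated correlation). In the authors' deposited table, 22 were called higher and 1 lower, COL6A2, with a log2 fold change of -1.20 there and too low to be tested by limma. The intermediate filament gene VIM rose 10.3-fold, from 62.8 ± 4.59 to 646 ± 20.3, the actin-binding gene TAGLN rose 36.4-fold, from 2.59 ± 0.422 to 94.3 ± 3.65, and the matrix gene FBN1 rose from 0.207 ± 0.0551 to 35.4 ± 0.763.

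Markers of fibroblasts, a cell type that shares matrix genes with the mesenchymal list (6 of the 16 markers are on both), rose in all 6 tested (8 of 16 members in the table, camera adjusted p = 0.0129, and adjusted p = 0.272 with an estimated correlation). LUM was 0.08 ± 0.0755 and 25.4 ± 1.76 (parental mean 0.045 without parental library 1), POSTN was listed at 0 in the parental libraries and was 4.43 ± 0.352 in resistant ones, and C1R rose from 41.3 ± 11.3 to 173 ± 8.51. Among YAP and TEAD targets 8 of 9 rose (9 of 20 members in the table, camera adjusted p = 0.0446, and adjusted p = 0.406 with an estimated correlation). CCDC80 rose from 2.23 ± 0.65 to 62.9 ± 5.36 and ANKRD1 from 7.59 ± 2.45 to 135 ± 1.93, while the ectonucleotidase NT5E fell from 93.1 ± 5.53 to 14.6 ± 0.632. The camera adjusted p of that list was 0.0517 without parental library 1, 0.0519 with a pseudocount of 0.1 and 0.0606 with genes filtered at a value of at least 5 (range over the alternatives 0.0317 to 0.0606). TGF-beta response genes split into 6 higher and 5 lower (camera adjusted p = 0.659). The activin subunit INHBA rose from 0.183 ± 0.0289 to 17.4 ± 1.1, TGFB2 rose from 13 ± 4.49 to 137 ± 6.62 and TGFBR1 rose from 4.9 ± 0.653 to 26.4 ± 0.98, while the cell cycle inhibitor CDKN1A fell from 16.6 ± 3.01 to 3.18 ± 0.207.

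**Figure D2:**
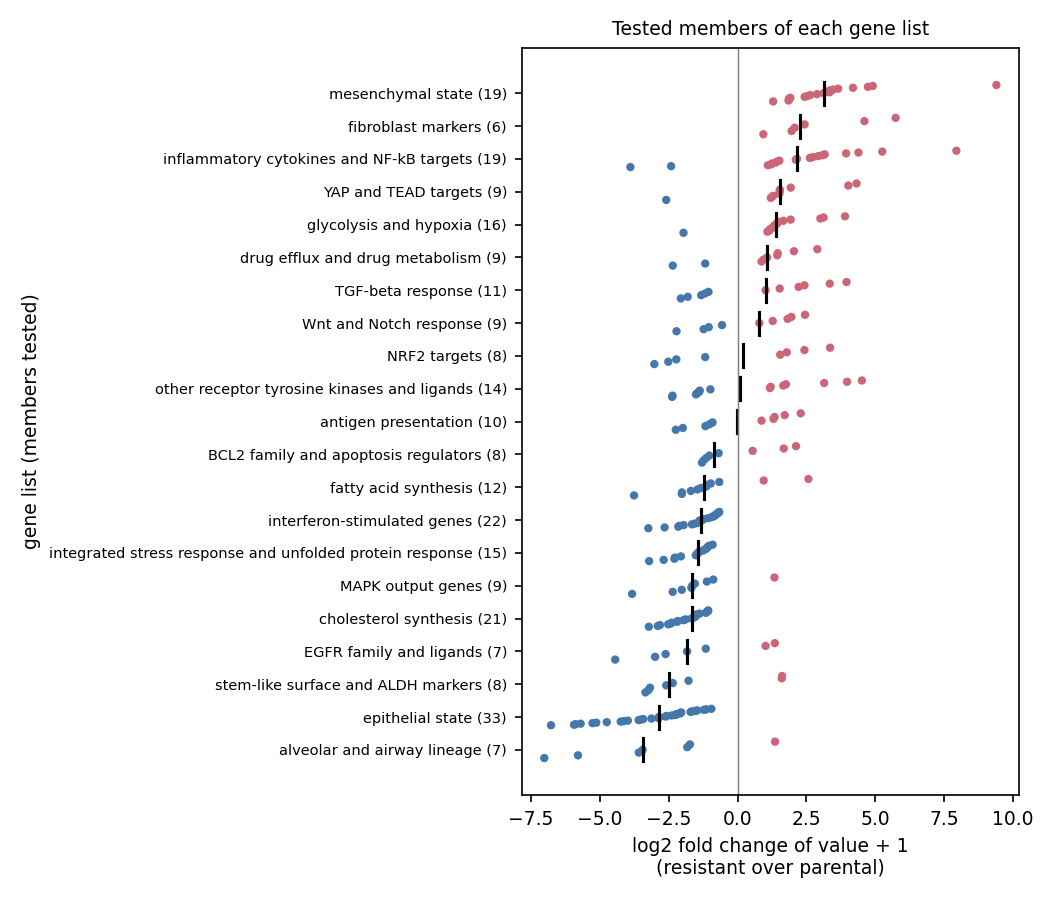
Log2 fold change of value + 1 (resistant over parental, horizontal axis) of the tested members of 21 gene lists (vertical axis, number tested in brackets), with a point per gene, red above 0 and blue below, and black bars at list medians. All 33 epithelial points lay below 0 and all 19 mesenchymal points above it.

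Genes of cholesterol synthesis fell in 21 of 21 tested (21 of 25 members in the table, camera adjusted p = 5.67e-06, and adjusted p = 0.406 with an estimated correlation). The sterol oxidase MSMO1 fell 6.02-fold, from 101 ± 3.09 to 16.9 ± 0.714, the squalene enzymes SQLE and FDFT1 fell from 35 ± 2.31 to 5.72 ± 0.194 and from 302 ± 50.5 to 39.3 ± 0.783, and DHCR7 fell from 127 ± 16.3 to 23.4 ± 1.61. SQLE lies on chromosome 8 beyond 50 Mb, where 113 of the table's genes fell and 19 rose. In this list parental library 3 had a median log2 value 0.38 above the other parental libraries, away from the resistant values. In fatty acid synthesis 9 of 12 tested genes fell, 2 rose and 1 was not called (13 of 17 members in the table, camera adjusted p = 0.0175, and adjusted p = 0.272 with an estimated correlation). The desaturase SCD fell 14.1-fold, from 415 ± 50.6 to 29.5 ± 0.956, and the regulator SREBF1 fell 4.16-fold, from 119.5 ± 10.2 to 28.7 ± 2.67, while ACSL1 rose from 2.38 ± 0.144 to 19.1 ± 0.207.

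Glycolysis and hypoxia genes rose in 15 of 16 tested (17 of 31 members in the table, camera adjusted p = 0.04, and adjusted p = 0.741 with an estimated correlation). The phosphofructokinase PFKP rose 2.47-fold, from 76.4 ± 19.4 to 189 ± 4.4, and the hexokinase HK1 2.71-fold, from 34.5 ± 14.8 to 93.5 ± 3.03. The hypoxia-inducible peptide ADM had 19.62, 14.76 and 70.49 in parental and 420.48, 414.98 and 444.33 in resistant libraries, a rise of 12.2-fold with all libraries and of 24.8-fold without parental library 3. The prolyl hydroxylase EGLN3 fell from 11 ± 10.1 to 1.54 ± 0.72, its parental mean being 5.18 without parental library 3. Parental library 3 stood apart in these genes, with a median log2 value 1.31 above the mean of the other parental libraries, against 0.13 over all tested genes. The list's median log2 fold change between the lines was 1.38, of similar size. The camera adjusted p was 0.0607 without parental library 1 and 0.0522 without parental library 2 (range over the alternatives 0.00106 to 0.0607). In oxidative phosphorylation 2 genes of 38 were in the table, CYC1 lower (from 118 ± 5.94 to 49.1 ± 1.66) and NDUFV2 higher (from 128 ± 24.6 to 327 ± 8.1). CYC1 lies on chromosome 8 beyond 50 Mb, where most genes of the table fell, and NDUFV2 on chromosome 18 up to 15 Mb, where 29 rose and 1 fell.

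Genes of the integrated stress and unfolded protein responses fell in all 15 tested (15 of 26 members in the table, camera adjusted p = 0.00247, and adjusted p = 0.618 with an estimated correlation). The serine synthesis enzyme PSPH, which lies in the stretch of lower genes beside EGFR on chromosome 7, fell 5.13-fold, from 125 ± 25.4 to 24.4 ± 1.82. CHAC1 fell 5.66-fold, from 34.3 ± 10.6 to 6.07 ± 0.6, and the folate enzyme MTHFD2 2.92-fold, from 179 ± 32.8 to 61.3 ± 4.17. Parental library 3 lay toward the resistant values here too, with a median log2 difference of -0.99 from the other parental libraries. The list's median log2 fold change between the lines was -1.42.

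Inflammatory genes rose in 17 of 19 tested (21 of 34 members in the table, camera adjusted p = 0.0129, and adjusted p = 0.618 with an estimated correlation). The cytokines IL6 and IL32 rose 22.4-fold and 46.9-fold, from 11.6 ± 2.79 to 260.2 ± 17.3 and from 4.27 ± 0.667 to 200.1 ± 7.42. The monocyte chemokine CCL2 fell 20.2-fold, from 54.1 ± 11.5 to 2.68 ± 0.538, and CXCL16 also fell. Parental library 3 had a median log2 value 0.83 above the other parental libraries in this list, whose median log2 fold change between the lines was 2.16. Interferon-stimulated genes fell in 19 of 22 tested, and 3 were not called (24 of 39 members in the table, camera adjusted p = 2.13e-04, and adjusted p = 0.433 with an estimated correlation). IFITM1 fell 12-fold, from 39.7 ± 6.07 to 3.31 ± 0.654, PARP9 3.36-fold, from 36 ± 1.38 to 10.7 ± 0.191, and IFI44L 5.07-fold, from 24.2 ± 1.76 to 4.78 ± 1.47. In this list parental library 3 differed by a median of 0.41 from the other parental libraries, away from the resistant values.

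Antigen presentation genes went both ways, 4 higher, 5 lower and 1 not called (camera adjusted p = 0.855). Their median was -0.02 and their mean 0.02. The class I gene HLA-B rose from 203 ± 52.5 to 984 ± 77.9, and the class II genes HLA-DRA and CD74 fell, from 7.41 ± 0.158 to 0.793 ± 0.335 and from 9.05 ± 0.761 to 1.54 ± 0.235. HLA genes are polymorphic and share reads, so their values are uncertain. In the list of alveolar and airway lineage genes 6 of 7 tested fell (13 of 27 members in the table, camera adjusted p = 0.0175, and adjusted p = 0.406 with an estimated correlation). The aspartic protease NAPSA fell 86.3-fold, from 146 ± 2.08 to 1.69 ± 0.635, the lung transcription factor NKX2-1 fell from 14 ± 1.73 to 0.253 ± 0.231 (resistant mean 0.12 without resistant library 3), and 1 gene of the list rose. In this list parental library 3 had a median log2 value 0.46 above the other parental libraries. The camera adjusted p was 0.0606 with genes filtered at a value of at least 5 (range over the alternatives 0.013 to 0.0606). Stem-like surface and ALDH markers fell in 6 of 8 tested (9 of 19 members in the table, camera adjusted p = 0.0279, and adjusted p = 0.272 with an estimated correlation), with SOX2 falling from 10.4 ± 0.506 to 0.12 ± 0.0436 and KLF4 from 25.8 ± 1.03 to 1.84 ± 0.0954, while CD44 rose from 174 ± 84.5 to 498 ± 22.1. Their camera adjusted p was 0.0762 without parental library 3 and 0.0606 with genes filtered at a value of at least 5 (range over the alternatives 0.013 to 0.0762).

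Drug efflux and metabolism genes were higher in 7 of 9 tested without passing as a list (camera adjusted p = 0.357). The efflux pump ABCB1 rose 2.95-fold, from 7.86 ± 1.01 to 23.2 ± 4.24, and the aldehyde dehydrogenase ALDH1A3 fell 5.5-fold, from 67.5 ± 11.9 to 12.3 ± 0.645. UGT1A6 and GSTA1, which share sequence with sister genes and are uncertain, rose from 0.607 ± 0.0902 to 5.7 ± 1.06 and from 7.5 ± 3.86 to 56.9 ± 3.73. NRF2 targets split into 4 higher and 4 lower (camera adjusted p = 0.979), with HMOX1 rising from 9.87 ± 2.41 to 36 ± 1.24 and SLC7A11 falling from 8.79 ± 3.35 to 1 ± 0.115. Parental library 3 had a median log2 value 0.51 above the other parental libraries in NRF2 targets. In the BCL2 family 3 rose and 5 fell (camera adjusted p = 0.659). BOK rose from 2.27 ± 0.431 to 13.2 ± 0.745 and BID from 14.4 ± 5.86 to 46.3 ± 4.19. BBC3 and BMF fell, from 16.9 ± 1.8 to 6.66 ± 0.841 and from 28.1 ± 4.56 to 13.2 ± 0.191. Wnt and Notch genes had 5 higher and 4 lower (camera adjusted p = 0.855), with WNT5A rising from 0.137 ± 0.0709 to 5.24 ± 0.845 and HES1 falling from 13.9 ± 0.831 to 2.23 ± 0.391.

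Lists with fewer than 5 tested members had no list test. The table held 1 of 45 cell cycle genes, TYMS, which rose from 43.8 ± 47.3 to 277 ± 6.79, or 16.7-fold in place of 6.32-fold without parental library 3, and which lies on chromosome 18 up to 15 Mb, where 29 genes of the table rose and 1 fell. Of squamous and basal genes KRT17 rose from 0.653 ± 0.295 to 26.4 ± 1.23 and KRT15 and KRT16 fell, KRT15 from 34.1 ± 5.24 to 4.18 ± 0.889. Of neuroendocrine genes SCG5 rose from 1.24 ± 0.323 to 42.1 ± 2.92 and DDC fell from 11.3 ± 2.67 to 0.84 ± 0.32. Of endothelial genes ROBO4 and TIE1 rose, to 4.03 ± 0.545 and 2.66 ± 0.675 (parental mean of TIE1 0.38, or 0.05 without parental library 1), and PECAM1 fell from 6.77 ± 2.92 to 1.08 ± 0.326. The leukocyte list had 1 tested gene, CSF1R, which rose from 0.68 ± 0.142 to 1.94 ± 0.178. The retina list had none tested, its 3 genes in the table lying at group means of at most 0.84. MT-CYB and RPL8 were the mitochondrially encoded and ribosomal protein genes in the table, and both fell, from 4237 ± 448 to 2200.3 ± 19 and from 2625 ± 397 to 1192 ± 28.9, RPL8 from chromosome 8 beyond 50 Mb. Of replication-dependent histone genes H2BC5 rose from 6.14 ± 1.44 to 14.8 ± 1.2 and H2BC21 fell from 7.71 ± 2.64 to 3.62 ± 0.284. Counts adjusted over the list alone equalled those over all genes for each of the 31 lists. This was likely among genes picked for differing. Of the 13 lists that passed camera 0 held with an estimated correlation, which gave 3 lists at an unadjusted p below 0.05. An exact test of the direction of the authors' calls, chosen after the data were seen, passed 11. The test fry, which sets a list's genes against no change, passed 19, among them NRF2 targets with 4 higher and 4 lower. Such a pass was likely among genes picked for differing and does not mean that a list moved one way.

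The genes next to EGFR on chromosome 7, singled out after their values were seen, were lower as well. From SEC61G to CHCHD2 (54752250 to 56106576 in GRCh38) the annotation placed 14 protein-coding genes, of which 13 were in the table and lower. Some of them overlap, ENSG00000249773 with ZNF713, MRPS17 with NIPSNAP2 and PHKG1 with SUMF2, so their falls may not be separate. SEC61G, a subunit of the protein translocation channel, fell from 8054 ± 2853 to 438 ± 32.7, LANCL2 from 141 ± 3.01 to 5.49 ± 1.15 and VOPP1 from 616 ± 167 to 34.2 ± 0.387. In the authors' deposited table the log2 fold changes were -4.27 for SEC61G, -4.63 for EGFR, -5.21 for LANCL2 and -4.21 for VOPP1. In the same authors' deposited table the values of ZNF713 and CHCHD2, farther along, were -3.27 and -2.01.

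**Figure D3:**
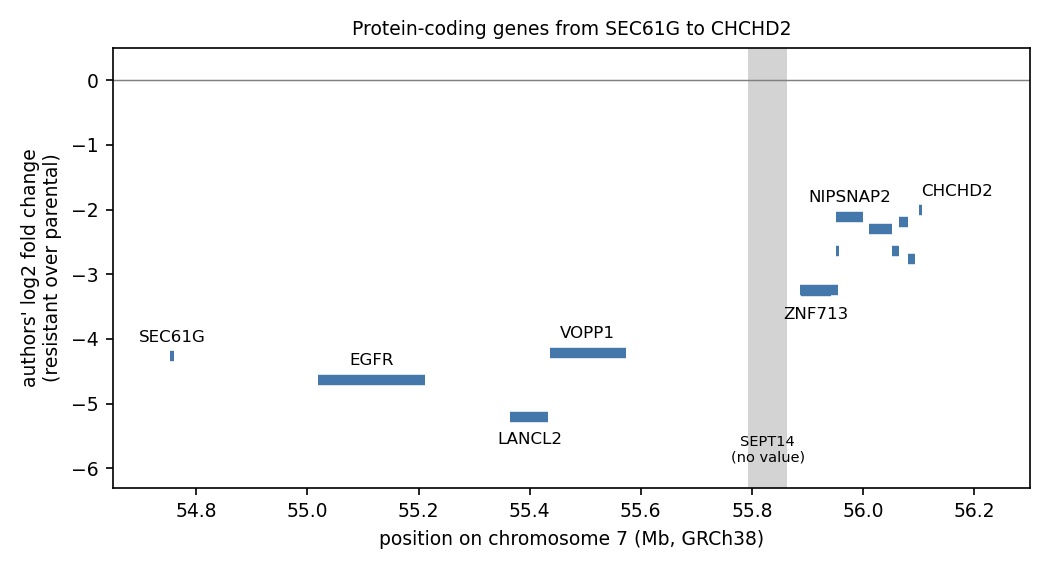
The authors' log2 fold change (resistant over parental, vertical axis) of the 13 protein-coding genes of the table from SEC61G to CHCHD2, drawn over their positions on chromosome 7 (horizontal axis, Mb, GRCh38), with a grey band at SEPT14, which has no value here. SEC61G, EGFR, LANCL2 and VOPP1 lay between -5.21 and -4.21.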

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

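The exact test of the direction of the authors' calls was chosen after seeing the data. The 1749 higher and 1500 lower genes stayed within 1.5 times of those counts under each alternative, except that a filter at a value of at least 5 gave 987 higher genes, and 939 higher by at least 2-fold in place of 1434, because fewer genes were tested. A pseudocount of 5 lowered the counts at 2-fold or more to 653 higher and 600 lower, from 1434 and 1110, since it shrinks the change of low genes. The 13 lists past camera became 8 with the filter at 5 and 5 at an adjusted p of 0.01. With the filter at 5, 4 lists lost their call, for which the cause was not tested, and fibroblast markers had fewer than 5 tested members and so no test. With an estimated correlation camera passed 0, and 3 at an unadjusted p below 0.05. The test fry, whose passes were likely among genes picked for differing, passed 19, and the exact test of direction 11. Leaving out each library in turn gave 1717 to 1758 higher, 1439 to 1508 lower, 1373 to 1439 and 1082 to 1116 at 2-fold or more, and 11 to 13 lists. Quantile normalization moved the median log2 fold change of the tested genes from 0.74 to 0.41, with a median change per gene of -0.102, and no gene named with a limma test changed direction under any alternative in which it was tested. The medians of 3 lists that did not pass, TGF-beta response, antigen presentation and other receptor tyrosine kinases, changed sign under at least 1 alternative. FGFR3, not called otherwise, passed with quantile normalization (-1.09), median centring (-1.04), without parental library 2 (-1.34) and without parental library 3 (-0.39). With the replicate number as a block the counts were 1750, 1508, 1433 and 1109, with 13 lists, and no call of a gene named with a limma test or of a list changed. Same-numbered libraries deviated with correlations of 0.026, 0.026 and -0.028, and differently numbered ones with -0.095 to 0.066. These values showed no pairing by number, but they cannot exclude a shared culture or day. Alternatives that need counts were not run. Depth is unknown, so no limit of detection can be given.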

Other observations

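The tests of chromosome regions, of the genes beside EGFR, of the epithelial share kept and of other splits of the libraries were chosen after their results were seen. On chromosome 8 beyond 50 Mb, 113 of the table's protein-coding genes fell, among them RPL8 and CYC1, and 19 rose (85.6% lower against 46.2% of the table's genes elsewhere, Fisher's exact p = 3.83e-20). Up to 50 Mb the same chromosome had 29 higher and 18 lower. On chromosome 18 up to 15 Mb, 29 genes rose, among them TYMS and NDUFV2, and 1 fell (Fisher's exact p = 9.75e-08), against 19 higher and 16 lower beyond. These bounds were set on the same data, so the p-values are too small. Over whole chromosomes, with Fisher's exact p adjusted over the chromosomes, chromosome 8 had 48 higher and 131 lower (adjusted p = 3.91e-11), chromosome 18 had 48 higher and 17 lower (0.00303), chromosome 5 had 102 higher and 46 lower (3.79e-04) and chromosome 11 had 85 higher and 115 lower (0.0257). These tests treat neighbouring genes as independent.

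The fullest window of higher genes lay on chromosome 19 (42313325 to 43465660), with 13 of 20 genes higher and 2 lower (permutation p = 0.014 by shuffled directions). It holds pregnancy-specific glycoprotein genes, whose near-identical sequences make their values uncertain. Among them PSG5 had the highest resistant mean, with a mean of 0.573 in parental and 27.7 in resistant libraries. The other such genes listed had resistant means from 0.263 (PSG6) to 1.93 (PSG8), and the shuffles counted each as a separate gene. Whether reads shared between them filled part of the window was not tested.

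In the log2 values parental libraries 1 and 2 had a Pearson correlation across genes of 0.991, and parental library 3 had 0.960 and 0.957 with them. Resistant libraries correlated at 0.990 to 0.991. Genes are not independent replicates. The authors' p-values and adjusted p-values imply about 21955 genes tested (21815 to 22059 over 96 genes) and a rank of about 8540 for the last gene listed, so about 4101 genes past 0.05 lie outside the table, which holds changes of at least 1 on the log2 scale.

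The real split of the 6 libraries gave 1749 higher and 1500 lower genes, 1434 and 1110 at 2-fold or more, and the highest of the other 9 splits gave 0 by limma, with at most 6 genes at an unadjusted p below 0.05. For the lists the real split gave 13 and the other splits 7 to 10. Camera at the preset correlation thus passed lists in mixed splits where no gene passed, which limits what the 13 list calls show. Each other split still holds unequal shares of the lines on its sides, so these passes are not a rate for unrelated groups. For each of these 5 results 1 of the 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05. The table's genes had also been picked for differing in the real split. Low gene counts in the other splits were therefore set by that selection, and the comparison cannot decide on chance.

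The genes beside EGFR fell with it. A window of 15 lower genes among 20 was reached in none of 1000 shuffles of direction (permutation p = 0.001, the smallest they can give). With EGFR left out the window from IKZF1 to CHCHD2 had 14 of 20 genes lower, reached in none of another 1000 shuffles (permutation p = 0.001). The first shuffles had 14 as their highest count. A window of 15 lower genes had to keep 14 without EGFR, so this p-value is no separate support. The shuffles also treat overlapping genes as separate. The values show that neighbours fell too, which lower transcription of EGFR alone does not cover. Fewer DNA copies of the region in the resistant line are a candidate explanation left open, since no DNA was measured and the 13 of 14 annotated genes that were lower are those that singled out the stretch. Another cell line in the resistant libraries cannot be told apart from selection for these genes, since the correlation of 0.6 between the line means comes from genes picked for differing.

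On chromosome 8, the window from MAPK15 to MROH1 had 14 of 20 genes lower (permutation p = 0.002 by shuffled directions, and by random placement 0.001, the smallest 1000 can give). Leaving out listed genes left 107 lower and 19 higher beyond 50 Mb (Fisher's exact p = 1.41e-19), against 113 lower and 19 higher with them. So few listed genes lay there that they could not account for the excess, and this p-value is no separate support for it. Falls in that stretch had a median of -1.53 against -2.04 elsewhere (permutation p = 0.0064), but the table holds only changes of at least 1 on the log2 scale and the bounds were set on the same data, so these sizes do not decide on a lower DNA dosage, which stays open. On chromosome 18 the window from CHMP1B to ZNF519 had 12 higher genes, with a permutation p of 0.001 by random placement but 0.0739 by shuffled directions, so a chance run stays open for that window, while the excess of higher genes over the whole chromosome had a Fisher's exact adjusted p of 0.00303. Rises up to 15 Mb were not shown to differ in size from those elsewhere (permutation p = 0.61), which under the same limits leaves dosage open as well.

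Epithelial genes fell while mesenchymal and fibroblast genes rose. If fibroblasts had been mixed into parental-like cells, the epithelial genes would keep about one share of their parental level, but the upper quartile of the share kept (21%) was 11.06 times the lower quartile (1.9%). The spread of the share kept argues against such a mixture as the whole cause, and a smaller one stays open. Fibroblast markers in the resistant libraries had means of 0.81 for COL3A1, 1.81 for DCN, 25.4 for LUM, 67 for FBLN1 and 173 for C1R. COL1A1, COL1A2, PDGFRA, FAP, THY1, PDPN, CXCL12 and MFAP5 were not in the table, so the authors had not called them at 2-fold or more. Their values are unknown, so the markers do not decide on a mixture. A change of state within the line remains a hypothesis, as does another cell line, whose genotype was not tested.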
